A study of Mus musculus with 8 samples.

How the data were processed

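Gene expression was measured in lungs of mouse embryos late in gestation on 8 Illumina bead arrays. The embryos were wild type or carried the mutation that the labels call SMRTmRID, shortened here to mRID. Their mothers ate control chow or a diet with 0.15% PTU for 2 days from embryonic day 16.5. The 4 groups are wild type on control chow, mRID on control chow, wild type with PTU and mRID with PTU. The labels call the 2 arrays of each group technical replicates, so each group was treated as 1 RNA sample measured on 2 arrays. How many embryos went into an RNA sample is not given in the sources used here. A difference between 2 groups is therefore a difference between 2 RNA samples, and its p-value covers array error and no variation between animals.

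Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment, and amplified to biotin-labelled cRNA. Per the submitters' processing notes, GenomeStudio was used, with no version stated. The first deposited table holds, per the file headers, an average signal for each probe and array, which is a linear intensity not normalized between arrays. It also holds a detection p-value for each probe and array, per the file headers. The second deposited table holds processed intensity values on a linear scale. Its column medians lay between 52.3 and 52.4 and its quartiles nearly coincided. The ranks of each array of the first table correlated at 1 with those of 1 of its columns. Normalization between arrays by the authors was therefore inferred from the values and is stated nowhere. Its column maxima ranged from 20397 to 25090, where plain quantile normalization would make them equal, so the method is not known. Its values were neither logged nor centred. The array columns of the first table carry a group name and a letter, while the titles carry a replicate number, so the arrays are named here by group and letter.

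The arrays had 25697 probes. Their mean signals ranged from 294 to 376, and between 54.7% and 58.8% of the probes had a detection p under 0.05. The 2 arrays of a group correlated at 0.997 in each group over 10298 genes, and arrays of different groups at 0.989 to 0.995. The median standard deviation (SD) between the arrays of a group was 0.07 on the log2 scale. The number of arrays limits the precision of every value.

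The main values were computed from the first table with limma 3.58.1 in R 4.3.3. The background was corrected by the normal-exponential method with the noise inferred from the detection p-values, an offset of 16 was added, log2 was taken and the arrays were quantile normalized (neqc). The offset shrinks the differences of dim genes. A probe was kept when its detection p was under 0.05 on both arrays of at least 1 group, which left 14965 probes. Gene names came from the platform annotation, in which 23978 probes had 1 symbol, 0 had several and 1719 were not listed and stay unnamed here. Of the named probes, 23962 were found by gene identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used for names and chromosomes alone, since no genome build is given for the array in the sources used here, and no coordinates are printed. Each gene was represented by its kept probe with the highest mean signal, which gave 10298 genes, 2720 of them with several kept probes. Of the 14965 kept probes, 899 had no gene name.

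One linear model with a mean per group was fitted to all 8 arrays with lmFit and eBayes, which left 4 residual degrees of freedom and a prior of 6.44. It gave 4 comparisons of 2 groups each and the genotype by diet term, which is the PTU difference in mRID minus the PTU difference in wild type. A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05 with a difference of at least 1.5-fold. A second model averaged the arrays of each RNA sample and fitted genotype and diet over the 4 RNA samples, with 1 residual degree of freedom and a threshold of 0.05 on the adjusted p. Its error lies between RNA samples. Log2 differences are given with the standard error (SE) of the fit. For a gene that was undetected on both arrays of the dimmer group, the fold is given as a lower bound against the lowest signal of detected probes on those arrays, or the gene's own value if that was higher.

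Before the data were examined, 26 gene lists were fixed. They cover type I pneumocytes, type II pneumocytes and surfactant, thyroid hormone responsive genes, the corepressor complex and nuclear receptors, retinoic acid and glucocorticoid responsive genes, Klf2 and its endothelial targets, proliferation, cyclin-dependent kinase inhibitors, club, ciliated, fibroblast, smooth muscle, endothelial, erythroid, macrophage and neutrophil markers, heart and skeletal muscle, thymus, liver, squamous epithelium, neuroendocrine and neural genes, hypoxia, immediate early and heat shock genes, fatty acid and sterol synthesis, and sex-linked genes. For each list the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. This percentile describes these RNA samples and is no test of the conditions.

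The rule for the genes named in the text was also fixed before the data were examined. It took the 8 largest differences each way for genotype on control chow and for PTU in mRID, and 4 each way for the other comparisons and the genotype by diet term, among genes that passed with the arrays of the 2 groups fully apart (for the genotype by diet term, passing was enough), leaving out clone and predicted names. For the fits over RNA samples it took 6 each way among genes that passed, or otherwise the 3 each way with the lowest unadjusted p. It took the 4 members of each list with the lowest p for genotype on control chow, and always Klf2, Pdpn, Aqp5, Ager, Sftpb, Sftpc, Thra, Thrb and Klf9. Thrb did not pass the detection filter and has no value. One further gene of that rule is not reported here.

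Chance values for shared arrays were obtained by simulating unchanged groups with the estimated array error, with 100 simulations for the share of genes that moved back. The fits were tested on simulated data with 200 changed genes in each of 20 draws over 10298 genes, with gene variances drawn from the estimated prior. For genotype on control chow, 46.7% of genes changed 1.5-fold, 98.9% of those changed 2-fold and 100% of those changed 4-fold passed, and 1.44% of the passing genes were unchanged ones. For genotype across diets the shares were 26.7%, 91.5% and 100%, and 13.1% of the passing genes were unchanged ones, above the 5% that the threshold stands for. Of 200 random lists of 12 unchanged genes, 10 (5%) lay outside the bounds of the central 95% for genotype on control chow. The genes were simulated independently, so a share near 5% follows from the setup. It gives no false rate for lists whose genes vary together. Alternatives were no background correction, median scaling, no filter or a stricter one, the deposited processed values, every kept probe tested by itself, an intensity trend, each array left out, the array letter as a block, other fold thresholds and the RNA sample as a random block. Figures were drawn with matplotlib 3.10.9. Probes without a gene name entered no comparison of genes.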

Results

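The data covered 4 lung RNA samples, each hybridised to 2 arrays: lungs of wild type and SMRTmRID embryos late in gestation, from mothers on control chow or on a diet with PTU. The mutant embryos are called mRID below. The title of the series links the mutation to type I pneumocytes, the flat cells of the gas-exchange surface, and to repression by the thyroid hormone receptor. The design allows the genotypes to be compared on each diet and the diets in each genotype. Values are normalized log2 signals of 10298 genes, differences are log2 differences with SE, and adjusted p-values are from limma with Benjamini-Hochberg adjustment. Because each group was 1 RNA sample, these tests compare RNA samples and not genotypes or diets.

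On control chow, the mRID RNA had less signal than the wild-type RNA for 5 of 6 squamous epithelial and 7 of 13 immediate early and heat shock genes, and the single largest difference was in a secretory gene of the airway. Scgb3a1, a secretoglobin of airway secretory cells, was 6.42-fold lower (-2.68, SE 0.11, adjusted p 8.84e-07). The squamous keratins Krt13 and Krt4 were 6.35-fold and 4.84-fold lower, and Psca and the antimicrobial lectin Reg3g were 3.56-fold and 3.6-fold lower. Ifit3, an interferon-induced gene, was 3.69-fold lower, and the growth-factor-induced genes Ier2 and Fos were 3.53-fold and 3.39-fold lower. In the other direction, Angptl4, an inhibitor of lipoprotein lipase, was 3.14-fold higher (1.65, SE 0.09). Crh, which encodes corticotropin-releasing hormone, was 2.63-fold higher, and Aspg, the histone gene H2ac11, Saa3, the embryonic globins Hbb-y and Hba-x, and Khsrp were 1.79-fold to 1.97-fold higher. In all, 164 genes passed, 45 higher and 119 lower in mRID, against 26 and 171 with median scaling and 20 and 75 without background correction.

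Of the type I pneumocyte list, 0 of 16 tested members passed for genotype on control chow, while 15 of 16 had a negative difference, with a median of -0.24 that lay at percentile 0 of random lists. Percentile 0 was not particular to this list. The Klf2, endothelial, club, heart and skeletal muscle, squamous, and immediate early and heat shock lists had it too. Col4a3 and Col4a4, collagens of the basement membrane, differed by -0.55 and -0.41 and missed the fold threshold, and Sec14l3 differed by -0.33 with an adjusted p of 0.0625. The water channel Aqp5 differed by -0.37, Ager by -0.25 and Pdpn by -0.15, with adjusted p-values of 0.0733, 0.255 and 0.383. Igfbp2 was the 1 member with a positive difference, 0.57. Of the type II and surfactant list, 0 of 19 members passed and the median was 0.08 at percentile 94.1. Sftpb and Sftpc, which encode surfactant proteins, differed by 0.36 and 0.14, Chil1 by 0.54, Ctsh by -0.19 and Egfl6 by 0.41.

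Klf2, a transcription factor of endothelium and lung, fell by 0.80 (SE 0.09, adjusted p 0.000792) and Klf4 fell by 0.65 in mRID on control chow. They were the 2 of 8 tested members of the Klf2 list that passed, and the list median was -0.27 at percentile 0. Thbd and Edn1 differed by -0.44 and -0.30 without passing. Of 13 endothelial markers, Car4 alone passed, at -0.65, and the median was -0.20. Ramp2, Tie1 and Emcn differed by -0.34, -0.23 and -0.20. Proliferation genes lay on the other side, with a median of 0.29 over 17 members at percentile 100 and positive differences in 16 of 17. Of these Plk1, a mitotic kinase, rose by 0.84 and the replication helicase subunit Mcm6 by 0.83, while Mcm3 and Mcm5 differed by 0.54 and 0.42 and missed the fold threshold. For the 6 cyclin-dependent kinase inhibitors the median was -0.12 (-0.05 without mRID control array B) and 0 passed, with Cdkn2b, Cdkn2c, Cdkn1a and Cdkn2d at -0.20, -0.19, -0.14 and -0.11.

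Immediate early and heat shock genes were the list with the most members that passed, 7 of 13, all lower, with a median of -0.60. Egr1 fell by 1.52 alongside Fos and Ier2, and Fosb was at least 1.77-fold lower, being undetected in mRID. Some squamous epithelial and muscle genes were lower as well. Of 6 squamous epithelial genes, with a median of -1.40, 5 were lower, among them Krt14 (-1.49) and Trp63 (at least 2.16-fold), and of 12 heart and skeletal muscle genes, with a median of -0.44 (-0.21 without mRID control array A), 5 were lower, including Myl4 (-1.05), Myh6 (-0.84), Myl7 (-0.80) and Tnni3 (-0.85). The smooth muscle list had a median of -0.24 with 1 of 8 members lower, Actg2 at -0.77, while Myh11, Tagln and Acta2 differed by -0.55, -0.42 and -0.24 without passing. Neutrophil genes had a median of -0.27 and 2 of 8 lower, Ltf (-0.77) and Camp (-0.66), with Mmp9 and Retnlg at -0.38 and -0.31. The club cell list had a median of -0.34, and past Scgb3a1 its members Cyp2f2 and Aldh1a1 differed by -0.41 and -0.35. Hypoxia-induced genes had a median of 0.21 at percentile 100 (0.11, inside the central 95% of random lists, without wild-type control array B), with P4ha1 higher by 0.62 and Egln3, Slc2a1 and Ddit4 at 0.54, 0.36 and 0.26 without passing.

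Of 10 tested members of the thyroid hormone responsive list 0 passed for genotype on control chow, and the median was 0.02 at percentile 58.3 (0.16, outside the central 95% of random lists, without mRID control array A), with Gpd2, Mbp, Atp2a2 and Bcl3 at 0.30, 0.30, -0.16 and 0.16. Klf9, a direct target of the thyroid hormone receptor, differed by -0.09. Thra was near the detection limit, detected on both wild-type control arrays and on 1 mRID control array, with a difference of -0.12. For the corepressor and nuclear receptor list the median was -0.05 (-0.11 to 0.04 with each array left out) with 0 of 15 passing, and Rara, Gps2, Rarb and Hdac3 differed by at most 0.27 in size. The glucocorticoid list had a median of -0.07 (-0.14 without wild-type control array A) and 1 of 13 lower, the phosphatase gene Dusp1 at -0.78, and Crispld2, Sgk1 and Tsc22d3 at -0.49, -0.44 and -0.43 missed the fold threshold.

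Among the remaining lists for genotype on control chow, 1 of 10 erythroid genes was higher (Hbb-y, 0.87, with Kel and Tspo2 at 0.49 and 0.47). The erythroid median was 0.11 (0.09 to 0.17 with each array left out). Of 15 fibroblast and matrix genes Wnt2 was higher by 0.61 and Lum, a small proteoglycan, lower by 0.98, with Eln and Tbx4 at -0.41 and -0.34 and the median at -0.09 (-0.01, inside the central 95% of random lists, without wild-type control array A). The medians of the retinoic acid, ciliated, macrophage, thymus, liver, neuroendocrine, fatty acid and sterol, and sex-linked lists were -0.18, 0.00, -0.14, -0.04, 0.14, -0.20, 0.13 and 0.00, and 0 of their members passed. Within these, Rarres2, Ccdc113, Lyz2, Thy1 and Stard4 differed by -0.34, 0.20, -0.26, -0.27 and 0.38.

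**Figure D1:**
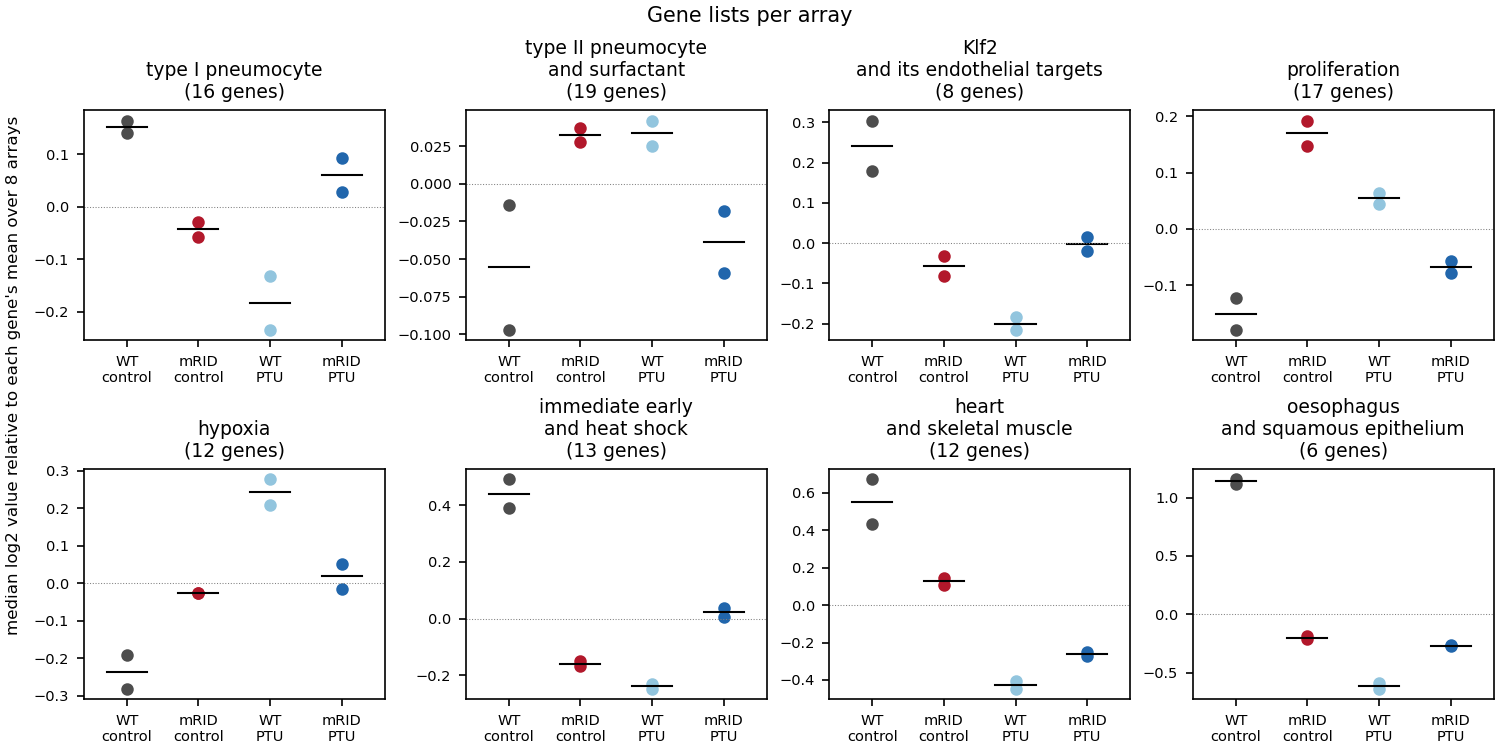
Median log2 value of 8 gene lists on each array, after subtracting each gene's mean over the 8 arrays (y axis, log2), by RNA sample (x axis); points are the 2 arrays and bars their mean. The type I list lies at 0.14 and 0.16 on the wild-type control arrays and at -0.06 and -0.03 on the mRID control arrays, and each panel has its own y scale.

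PTU in wild type gave differences in much the same direction as those of genotype on control chow. Paip1, which encodes a poly(A)-binding protein partner, fell by about 4.19, a size that is not exact because 1 of the 2 wild-type PTU arrays did not detect it, and Scgb3a1 fell by 4.25. Krt13, Krt4 and Psca were undetected on the wild-type PTU arrays and at least 8.81-fold, 10.2-fold and 9.1-fold lower. Crh was 8.35-fold higher, Angptl4 3.67-fold, Saa3 3.21-fold and Lor 2.61-fold. In all, 363 genes passed, 113 higher and 250 lower. Of the type I list 5 of 16 members were lower, among them Col4a3 (-0.93), Col4a4 (-0.83) and Aqp5 (-0.59), 1 was higher (Igfbp2, 0.76), and the median was -0.38 at percentile 0. The club, smooth muscle and endothelial lists moved the same way, with medians of -0.643, -0.375 and -0.221. They had 5 of 8, 2 of 8 and 1 of 13 members lower and 0 higher. Klf2 fell by 0.96, Klf4 by 0.64, Car4 by 1.14, Fos by 1.74 and Egr1 by 1.53. Plk1 and Mcm6 rose by 0.91 and 0.67, and Egln3, P4ha1 and Slc2a1, of the hypoxia list, rose by 1.16, 0.78 and 0.62. Of the type II list Chil1 alone passed, at 0.84. The heart and skeletal muscle list had 6 of 12 members lower with a median of -0.84 (-0.43 without wild-type control array A), and the squamous list 5 of 6 lower. The thyroid hormone responsive list had 0 of 10 passing and a median of -0.08, with Klf9 at -0.44 below the fold threshold. The sex-linked genes differed too: Xist was higher by 0.99 and the Y-linked Eif2s3y and Kdm5d were lower by 0.63 and 0.72 in log2 terms, while Uty differed by -0.15. The mix of sexes in the RNA samples was not tested.

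Across genes, the genotype difference on control chow and the PTU difference in wild type correlated at 0.738, where unchanged groups gave 0.5 because both use the wild-type control arrays. Their covariance was 0.0453 against 0.00588 from the shared arrays. Of the genes that passed in both, 122 had the same direction and 0 the opposite, where independent lists would give 3.4 and 2.4, a reference that leaves out the shared arrays. With 1 wild-type control array for each difference, a split made after the result was seen, the correlation was 0.543 and 0.564, and 106 and 108 genes passed in both in the same direction and 0 in the opposite. The 2 arrays hold the same RNA sample, so part or all of the excess may still come from it. The root mean square difference between the mRID control and wild-type PTU RNA, 0.19, was the smallest of the 6 pairs, the others being 0.22 to 0.28.

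PTU in mRID shared some genes with PTU in wild type: 31 passed in both in the same direction and 26 in opposite directions, against 4.9 and 7.2 for independent lists. Zc3h13, a zinc finger gene, rose by 2.16 (SE 0.12, adjusted p 4.8e-06), which is 4.48-fold. The insulin receptor substrate Irs2 was 3.99-fold higher, the transcription factor gene Bbx 3.56-fold, Man2a2 3.17-fold, Lims1 3.1-fold, the skeletal actin Acta1 3.09-fold, the RNA helicase Ddx6 3.07-fold and Atxn1 3.05-fold. Paip1 fell by 1.94, Reg3g by 1.72, the integrin gene Itga9 by 1.64, the cardiac light chain Myl3 by 1.60, Scgb3a1 by 1.49, Lum by 1.46, Aspg by 1.45 and the erythroid gene Trim10 by 1.44. In all, 342 genes passed, 258 higher and 84 lower. Of the type I list, 1 of 16 members was higher (Sec14l3, 1.08, which is also on the club list) and 1 lower (Igfbp2, -0.80). Differences were positive in 14 of 16 members, and the median was 0.10 at percentile 99.2. Without mRID PTU array A that median was 0.07, inside the central 95% of random lists. Pdpn, Aqp5 and Ager differed by 0.00, -0.23 and 0.21. Klf2 differed by 0.21 (SE 0.09, adjusted p 0.174) and did not pass, and Edn1 rose by 0.81. Fos and Egr1 rose by 1.00 and 0.86. The proliferation list had a median of -0.27 (0 of 17 passing), with Mcm3, Mcm5 and Mcm6 at -0.39, -0.40 and -0.35. Sftpb fell by 0.65 and Sftpc differed by -0.09. Klf9 and the sterol transfer gene Stard4 rose by 0.61 and 0.67. The thyroid hormone responsive list had a median of -0.14 at percentile 3.29 (-0.20 to -0.06 with each array left out, outside the central 95% of random lists in 2 of the 8 cases), with 6 of 10 differences negative and Klf9 the 1 member that passed. Of 4 liver genes 2 were higher, Ahsg by about 1.33 (detected on 1 of 2 mRID control arrays) and Ttr at least 1.96-fold, with Afp and Apoa1 short of the threshold. The erythroid list had 4 of 10 lower, including Kel (-1.40) and Hbb-y (-0.68), and the heart and skeletal muscle list had 5 of 12 lower and 2 higher.

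**Figure D2:**
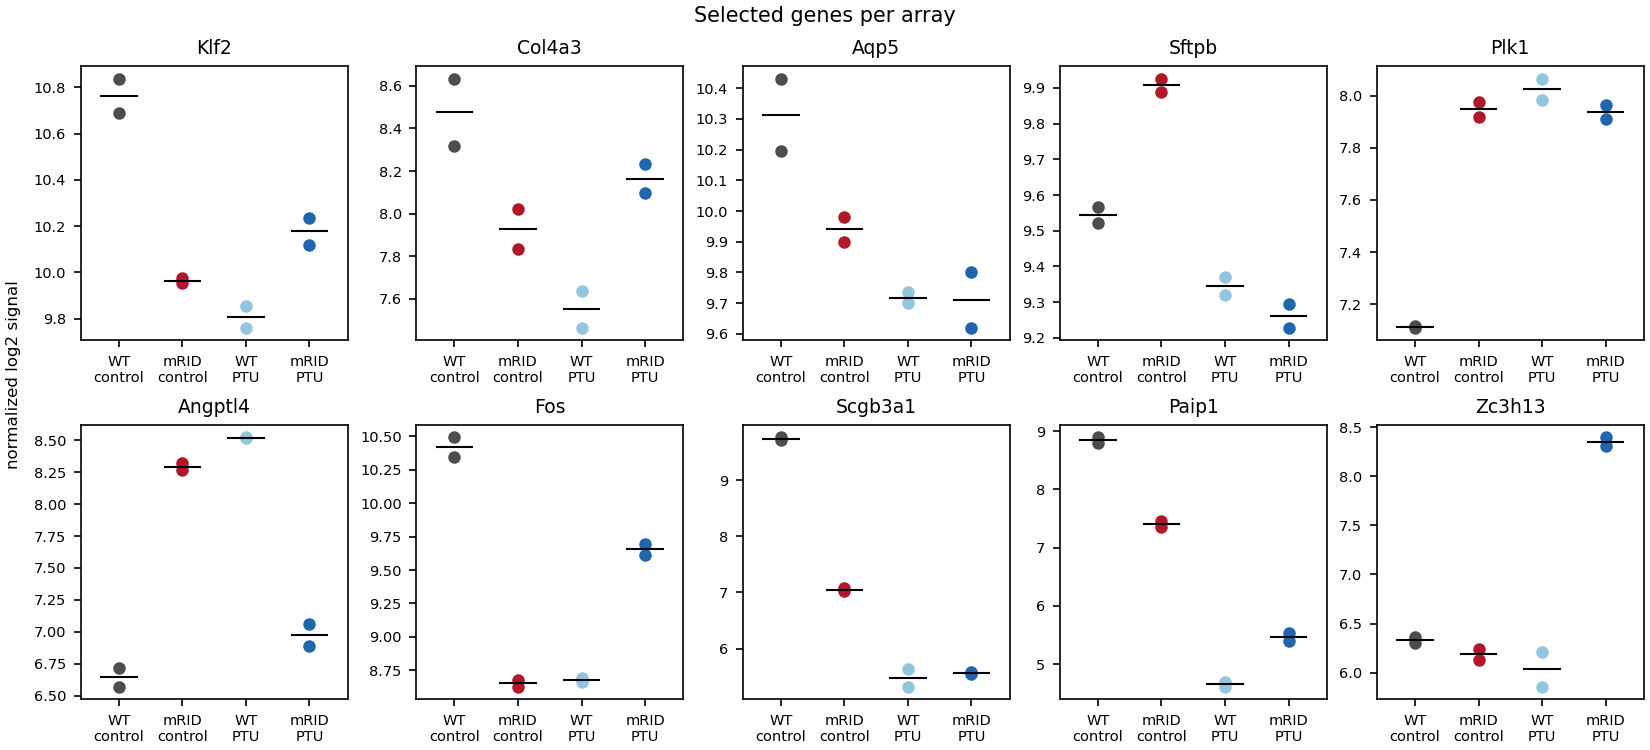
Normalized log2 signal (y axis) of 10 genes on each array, by RNA sample (x axis); points are the 2 arrays and bars their mean, and each panel has its own y scale. Klf2 averages 10.76 in the wild-type control RNA and 9.96, 9.81 and 10.18 in mRID control, wild type with PTU and mRID with PTU, while Zc3h13 averages 8.35 with PTU in mRID and at most 6.33 in the others.

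Whether PTU moved the genotype difference back in mRID was asked of the 164 genes that passed for genotype on control chow. Of these, 102 (62.2%, Wilson 95% interval 54.6% to 69.3%) had a PTU difference in mRID of the opposite sign. The interval takes the genes as independent, which they are not, so it may be too narrow. Simulated data with no PTU effect gave 63.2% on average (54.5% to 73.1% over 100 simulations), because both differences share the mRID control arrays. With the genes chosen on 1 mRID control array and the PTU difference taken from the other, the share was 54.3% and 60.4%. The pooled share lay within the simulated range. All these simulations hold array error only, without the deviation of the mRID control RNA sample that both of its arrays share. That deviation can raise the share with no PTU effect, so neither the simulations nor the split by array can show an effect of PTU. By direction, a split made after the result was seen, 35 of the 45 genes higher in mRID (77.8%) moved back, a share reached by 1 of the 100 simulations (50.6% to 78.6%), with 13 passing in the opposite direction and 0 in the same. Of the 119 lower genes 67 (56.3%) moved back, a share reached by 91 simulations (53.5% to 71.6%), with 15 passing in the opposite direction and 18 in the same. By the test of single genes, 28 of the 164 also passed in the opposite direction in PTU in mRID and 18 in the same direction. Angptl4, Aspg, Hbb-y, Rbp7, Fos, Ier2, Egr1 and Ifit3 passed in opposite directions, whereas Scgb3a1, Krt13, Reg3g, Psca, Itga9, Lum and Paip1 were lower in both.

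With PTU, the mRID RNA had more signal than wild type for most genes that passed. Zc3h13 was 4.98-fold higher, the myosin gene Myh8 4.09-fold, Eif4ebp2 3.92-fold and Bbx 3.8-fold. Tnfrsf10b was 3.1-fold lower, Angptl4 2.92-fold, Aspg 2.75-fold and Crh 2.58-fold. In all, 429 genes passed, 361 higher and 68 lower. Of the type I list 4 of 16 members were higher, including Sec14l3 (1.21, also on the club list), Col4a4 (0.62) and Col4a3 (0.61). In the same list 1 was lower (Igfbp2, -0.99), and the median was 0.26 at percentile 100. Liver (2 of 4), club (2 of 8) and immediate early (4 of 13) genes were higher as well, with medians of 0.71, 0.20 and 0.20. The hypoxia list went the other way, with 2 of 12 lower and a median of -0.25. Klf2 differed by 0.37 (adjusted p 0.0248), under the fold threshold. Klf9 and Gpd2, of the thyroid hormone responsive list, rose by 0.96 and 0.89, Hr was lower, and the median of that list was -0.07. Kel and Hbb-y were lower by 1.26 and 0.99 in log2 terms. Of the 10 erythroid genes 3 were lower and 2 higher, including Hbb-b2 (0.62), with a median of -0.16. Among sex-linked genes, Xist was lower by 0.71 and Kdm5d higher by 0.70, while Eif2s3y differed by 0.57 below the fold threshold.

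The genotype by diet term, which compares the PTU difference between the genotypes, passed for 972 genes, 636 positive and 336 negative. Ifit3 (3.15), Ier2 (2.95), Scgb3a1 (2.76) and Fos (2.74) had the largest positive terms, and Angptl4 (-3.19), Crh (-2.76), Aspg (-2.44) and Rbp7 (-2.10) the largest negative ones. The type I list had 5 of 16 members positive and 1 negative, with a median of 0.48. Larger medians came from the squamous (1.74), heart and skeletal muscle (0.84), and immediate early and heat shock lists (0.74). These had 5 of 6, 9 of 12 and 9 of 13 members positive and 0 negative. The Klf2 list had 4 of 8 positive, including Klf2 (1.17) and Edn1 (1.15), and the proliferation list 4 of 17 negative, including Mcm6 (-1.02) and Plk1 (-0.92). The genotype differences on the 2 diets, which share no arrays, correlated at -0.259 across genes, with 40 genes passing in opposite directions and 6 in the same direction, against 4.5 and 2.4 for independent lists. The PTU differences in the 2 genotypes, which share no arrays either, correlated at -0.055. Genes are not independent replicates, so these correlations carry no p-value.

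**Figure D3:**
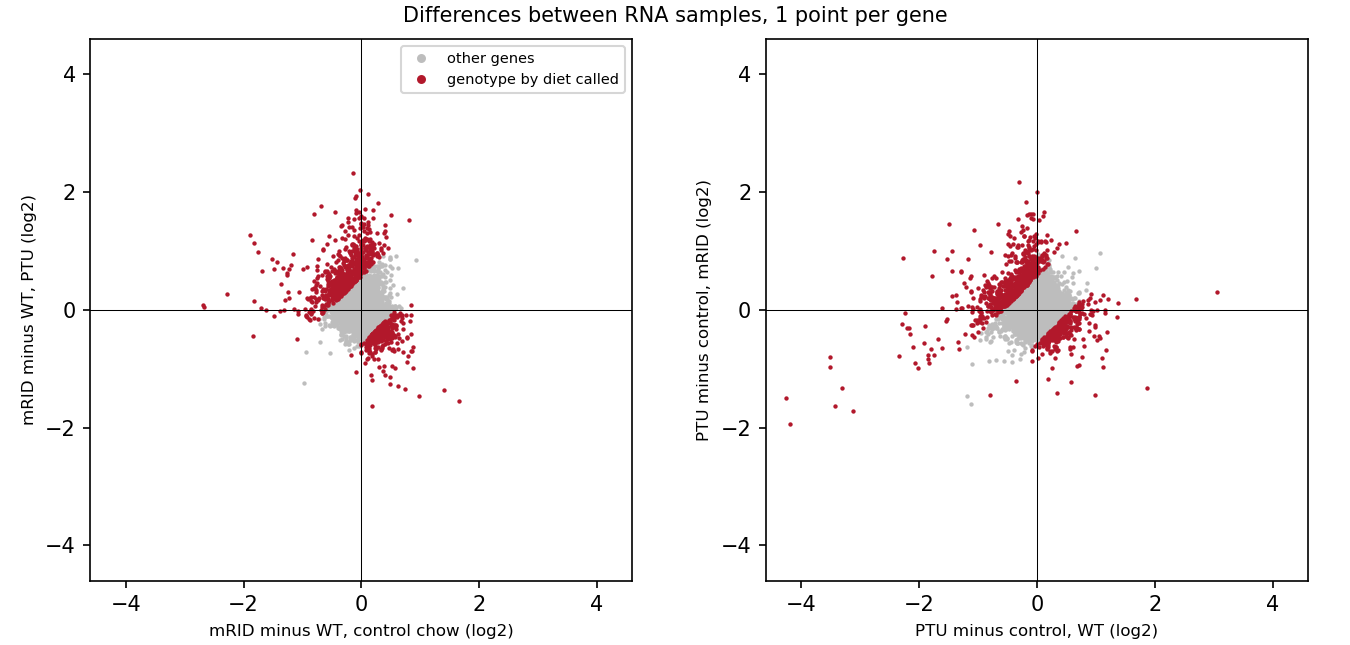
Log2 differences of 10298 genes, with genotype on control chow (x axis) against genotype with PTU (y axis) on the left and PTU in wild type (x axis) against PTU in mRID (y axis) on the right; each point is 1 gene, and the 972 genes that passed for genotype by diet are red. The correlation is -0.259 on the left and -0.055 on the right.

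The fit over the 4 RNA samples, with the error between them, passed 0 genes for genotype across diets and 0 for diet across genotypes with limma. At an unadjusted p under 0.05 it had 249 and 334 genes, where 515 are expected by chance, and the lowest adjusted p-values were 0.714 and 0.112. The error of this fit is the genotype by diet term, which passed for 972 genes in the fit to 8 arrays. Any such difference raises the error, so the 0 genes do not show that genotype and diet had no effect. With p adjusted over each list alone, diet passed for 7 of 12 heart and skeletal muscle and 3 of 4 liver genes. It also passed for 3 of 6 squamous, 3 of 8 club, 2 of 15 fibroblast and 2 of 10 erythroid genes. Genotype passed for 2 of 4 liver and 1 of 15 fibroblast genes, and 0 members of the lists not named here passed. These p-values are not adjusted across the 26 lists. The genes with the lowest p for genotype were H2ac11 (0.89), Epb41l5 (1.16) and Prf1 (0.75) on the positive side and Lum (-1.11), Sox21 (-0.83) and Inmt (-0.79) on the negative side. For diet they were Nudt9 (1.02), Slc10a6 (0.85) and Ahsg (1.00, undetected in wild-type control), and Lum (-1.32), Reg3g (-2.42) and Myl3 (-1.36). With all 8 arrays and the RNA sample as a random block, 6 and 41 genes passed. That fit takes part of its degrees of freedom from technical arrays, so these counts are too liberal as a comparison of genotypes or diets.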

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

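The genotype by diet term and the genotype differences on each diet were planned, the test of other probes was fixed before its share was computed, and the other tests of explanations were chosen after the result was seen. The results below had PTU differences that differed between the genotypes, by the genotype by diet term of the fit to 8 arrays, and 1 came from probes outside the gene comparisons. Each group is 1 RNA sample, so the term compares RNA samples.

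The genotype by diet term passed for 972 genes, and 40 genes passed for genotype in opposite directions on the 2 diets. Among the named genes of that kind, those lower in mRID on control chow and higher with PTU were Ifit3 (term 3.15), Ier2 (2.95), Fos (2.74), Egr1 (2.39), Paip1 (2.25), Krt14 (2.18) and Car4 (1.68). Krt14 was detected on 0 and Paip1 on 1 of the 2 wild-type PTU arrays, so their terms are no exact sizes. Those higher on control chow and lower with PTU were Angptl4 (-3.19), Crh (-2.76), Aspg (-2.44), Rbp7 (-2.10), Hbb-y (-1.86), Hba-x (-1.55), Saa3 (-1.50) and P4ha1 (-1.28). Of 899 kept probes without a gene name, 102 passed for genotype by diet.

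Several heart and squamous epithelial genes were higher in the wild-type control RNA than in the others, while Myl2, Sprr1a and Acta1 were not. A single neighbouring tissue carried along at dissection is a candidate explanation. It needs 1 common ratio for both sets only if the lung itself did not express these genes, which was not tested. The 9 cardiac and 6 squamous genes detected there differed by a median of -0.80 and -1.40 between the control RNA samples. The exact permutation p of the difference between medians was 0.0615 on the normalized scale and 0.00799 after subtracting the offset, over 5005 splits. The result depends on the scale and the test takes the genes as independent, so the explanation stays open. Heart muscle as 1 source of the cardiac genes also stays open, since 55.6% of the 9 genes (5) lay within 0.5 of their median log2 ratio in all 3 comparisons, and lower expression by genotype or diet was not tested.

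A set of 211 genes, led by Zc3h13 and Bbx, passed as higher in mRID with PTU against both mRID on control chow and wild type with PTU. Normalization between arrays may be one cause, but 202 of them (95.7%) also passed both ways with median scaling, which argues against the quantile step. Median scaling kept the same background correction, so it cannot address a difference in signal over background. The median signal was 1.43 and 1.48 times that of undetected probes on the mRID PTU arrays. It was 1.36 and 1.37 times on the mRID control arrays and 1.36 and 1.41 times on the wild-type PTU arrays. On the wild-type control arrays it was 1.48 and 1.42 times. Probes that respond without their gene could be another: of 75 other kept probes of these genes 77.3% were positive in both comparisons, against 31.4% of the other kept probes of all other genes. Of the 75 probes, 33 also passed as higher in both comparisons. The share of 77.3% lies short of the 80% set beforehand to exclude the explanation, so the explanation stays open. With the deposited values 150 of the genes (71.1%) passed both ways. The genes were dim, with a median of 6.25 in the other RNA samples against 7.44 for all genes, and an effect of genotype with diet was not tested.

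The medians of the type I list were lower and those of the proliferation list higher in the mRID control and wild-type PTU RNA than in the wild-type control RNA, with 0 and 5 of 16 type I genes passing as lower and 2 and 2 of 17 proliferation genes as higher. If the wild-type control RNA alone stood apart, the other 3 would be alike, and against mRID with PTU the type I medians were -0.10 in mRID control and -0.26 in wild type with PTU, and the proliferation medians 0.27 and 0.10. With each array left out, percentiles among random lists were at least 99.99 for proliferation in mRID control and at most 0.02 for type I in wild type with PTU, and reached 4.23 for type I in mRID control and 97.04 for proliferation in wild type with PTU. Over all genes the mRID PTU RNA lay 0.255 to 0.28 (root mean square) from the others, and the wild-type control RNA 0.216 to 0.284. The wild-type control RNA thus did not stand apart alone over all genes. For the type I and proliferation lists the explanation stays open, because the percentiles hold no spread between RNA samples. Lungs of an earlier developmental stage are another candidate explanation, with 2 of 3 embryonic globin genes (Hbb-y and Hba-x) passing in both, but these had been seen before the test and rest on array error, so this, a difference between litters and an effect of genotype or diet stay open.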

How the results depend on the processing

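The own-arrays fit and the fit of the deposited values with a replicate block were chosen after seeing the data. No setting changed the direction of a correlation. Other fold thresholds moved the counts by construction: at 2-fold 34, 120, 91, 79 and 232 genes passed for genotype on control chow, genotype with PTU, PTU in wild type, PTU in mRID and genotype by diet, and without a fold threshold 499, 1303, 1220, 1066 and 1619. Without background correction genotype on control chow had 95 genes and PTU in mRID 215, and with the deposited values 94 and 218, against 164 and 342; the cause was not tested. The same 94 and 218 came with the titles' replicate number as a block. The share moved back was 54.3% with the deposited values. The correlation of genotype differences on the 2 diets was -0.285 without background correction, -0.284 with the deposited values, -0.299 with detection on all arrays, -0.238 with every probe, -0.240 with median scaling and -0.243 without a filter. That of PTU differences was -0.077, -0.076 and -0.108 under the first 3 of these. With the RNA sample as a random block, 6 genes passed for genotype across diets and 41 for diet across genotypes, but that fit takes part of its degrees of freedom from technical arrays. With each array left out in turn, the counts ranged from 144 to 173, 425 to 476, 360 to 411, 336 to 372 and 916 to 1027 in the order above, both fits over RNA samples stayed at 0, the correlations ranged from -0.247 to -0.235 and from -0.061 to -0.044, and the share moved back from 58.5% to 68.2%. Median scaling changed the share of higher genes for genotype on control chow from 27.4% to 13.2%. With the array letter as a replicate block, 165, 431, 364, 342 and 988 genes passed; deviations of arrays with the same letter correlated between -0.064 and 0.113, so the letters were not taken to pair arrays. Among list medians outside the central 95% of random lists in the main setting, those that changed sign were glucocorticoid responsive genes for genotype with PTU (-0.069 with median scaling), retinoic acid responsive genes for genotype by diet (-0.051 without a filter) and erythroid genes for genotype with PTU and genotype by diet (0.061 and 0.020 with detection on all arrays), and the cause was not tested. Other list medians near 0 also changed sign with an array left out, for example thyroid hormone responsive genes for genotype by diet (-0.160 to 0.040). The hypoxia median for genotype on control chow fell from 0.211 to 0.112 without wild-type control array B, and the type I median for PTU in mRID from 0.103 to 0.067 without mRID PTU array A, both then inside the central 95% of random lists. The heart and skeletal muscle median went from -0.438 to -0.210 for genotype on control chow without mRID control array A, and from -0.843 to -0.430 for PTU in wild type without wild-type control array A. Signal over background limits dim genes: the median signal was 1.36 to 1.48 times that of undetected probes. It was 1.42 to 1.48 times in the wild-type control and mRID PTU RNA. In the mRID control and wild-type PTU RNA it was 1.36 to 1.41 times. These 2 pairs take opposite signs in the genotype by diet term, and a part of signal over background in that term was not tested.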

Other observations

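The interferon test below was fixed before its genes were looked at, on members not yet seen, while the histone and MHC families and the single genes were chosen after their values were seen.

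Interferon-response genes had negative median differences from the wild-type control RNA in mRID control and in wild type with PTU. After Ifit3, Rsad2, Oas2 and Ifi27l2a had been seen to be lower in mRID on control chow (-1.88, -1.27, -1.20 and -1.69), a list of 25 other interferon-response genes was drawn up, 19 of which were tested. Their median difference was -0.46 for genotype on control chow (3 of 19 lower, 0 higher) and -0.65 for PTU in wild type (10 lower, 0 higher), and the higher of the 2 percentiles among random lists was 0. This is consistent with a shift of these genes as a group, as a hypothesis about these RNA samples. For genotype with PTU the median was 0.42, with 6 members higher and 0 lower, and 16 of 19 passed for genotype by diet. PTU in mRID had a median of 0.25, with 1 member higher and 0 lower. Infection, litter and dissection were not tested.

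Of 38 replication-dependent histone genes tested, 9 were higher and 1 lower for genotype on control chow, with a median of 0.40, and 0 were higher and 6 lower for PTU in mRID, with a median of -0.23. For genotype with PTU 5 were higher and 0 lower with a median of -0.09, and for PTU in wild type 1 was higher and 1 lower with a median of 0.13. MHC class II genes, which present antigen, had a median of -0.73 for PTU in mRID, with 4 of 6 lower, among them Cd74 (-0.81), H2-Aa (-0.86) and H2-Eb1 (-0.88). Their median was 0.38 for genotype on control chow (1 higher, Cd74 at 0.69), -0.26 for PTU in wild type (1 lower, H2-Aa at -0.69) and -0.04 for genotype with PTU (0 passing).

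Paip1 averaged 8.84 in the wild-type control RNA, 7.40 in mRID control, 5.46 in mRID with PTU and 4.65 in wild type with PTU, where 1 of 2 arrays detected it. Itga9 averaged 8.98, 7.62, 5.98 and 5.54 in the same order. Xist averaged 6.55, 6.69, 6.83 and 7.54, and the Y-linked Kdm5d 7.67, 7.63, 7.65 and 6.95. The wild-type PTU RNA thus had the highest Xist and the lowest Kdm5d signal. A difference in the mix of sexes was not tested and cannot be told apart from other differences of that RNA sample. Such a difference would enter each comparison with that RNA sample and the genotype by diet term. Genes on the X and Y chromosomes made up 10 of the 363 genes that passed for PTU in wild type, and their share of all tested genes was not computed.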
